A study of Mus musculus with 16 samples.

How the data were processed

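RNA sequencing of mouse spleen was the assay of the series. The labels describe polyadenylated RNA from 16 spleen samples in 4 groups of 4. The groups were wild type under study code NG66, wild type under study code NG108, a triple knockout of Zfp36 and both TNF receptors, and a double knockout of both TNF receptors. Per the submitters' processing notes, TopHat2 2.0.4 and genome build mm10 were used. The counting method, the annotation source and the strandedness of the libraries are not given in the sources used here.

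The deposited file used here is a gene annotation for mm10. It has 595686 lines, of which 284820 are exons, 256983 coding segments, 26950 start codons and 26933 stop codons. The score field was empty on all lines, 0 lines carried an expression attribute, and 0 columns belonged to a sample. Expression in the 16 samples was therefore not analysed here. Depth per sample is unknown, and no fold change, error between replicates or test between genotypes is reported. The comparisons of genotypes that had been planned with edgeR's quasi-likelihood test or limma, and all of their alternatives, were not run.

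What was computed describes the annotation, in which genes are the units and no mouse contributes a value. Coordinates are 1-based on mm10. A 3' UTR was taken as the exonic bases downstream of the stop codon in a transcript with complete start and stop codons. Each gene was represented by its longest 3' UTR. Of 20508 gene symbols with a coding segment, 18715 had such a 3' UTR. Bases were taken from the transcript sequences of GENCODE M21, which is on GRCm38, the same assembly as mm10, placed on the genome by their exon coordinates. The plan had asked for a genome sequence, so this source is a departure from it. Overlapping transcripts of that reference disagreed at 0 bases, and 99.9% of 26792 looked-up stop codons of the deposited annotation read as a stop. A 3' UTR was searched only when every base was covered, which left 15846 genes (84.7% of those with a 3' UTR); where a gene's longest 3' UTR was not covered, the longest covered one was used for the site search.

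Before the data were examined, 16 gene lists with 139 genes were fixed from general knowledge of TTP biology, spleen cell types and possible contaminating tissues. They were the TTP family, the TNF receptors, known TTP targets, NF-kB and TNF response, interferon response, granulocyte and myeloid, erythroid, B cell, T cell, NK cell, red pulp macrophage, dendritic cell, plasma cell, proliferation, pancreas and adipose. Membership of the known-target list rests partly on published AU-rich elements, so a test for such elements in that list is not independent evidence. The rule for named genes, fixed at the same time, took the 3 genotype genes, the other TTP family genes, and the 5 known targets with the longest and the 5 with the shortest 3' UTR. Some single genes of the fixed lists are not reported here.

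The difference in median 3' UTR length between targets and other genes was tested with a two-sided permutation test of 100000 resamples. The share of genes with at least 1 TATTTAT heptamer was set against 10000 random lists matched on 3' UTR length decile. These were drawn from genes outside the list, and the two-sided p is called the random-list p. These 2 tests were adjusted together by the Benjamini-Hochberg method. The same heptamer test was run on each of the 14 lists with 3 or more searched genes, adjusted over those lists. Both tests were tried on simulated lists of 25 genes drawn from the 15846 searched genes, with only 1000 random lists or resamples per run. The heptamer test called 20 of 20 lists given the site in 90% of members and 6 of 100 unchanged lists at p under 0.05. The length test called 19 of 20 lists with 3-fold longer 3' UTRs and 8 of 100 unchanged lists. Alternatives were the shortest or median 3' UTR per gene, the other fixed lists as background, a nonamer and a pentamer. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.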

Results

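The series concerned tristetraprolin (TTP, encoded by Zfp36), a zinc finger protein that binds AU-rich elements in 3' UTRs and promotes decay of the bound mRNA. Spleen RNA from 16 mouse samples was sequenced. There were 4 wild-type samples under study code NG66, 4 wild-type samples under study code NG108, 4 samples of a triple knockout (Zfp36, TNFR1 and TNFR2) and 4 of a double knockout (TNFR1 and TNFR2). The design text set the difference between triple knockout and wild type beside the difference between double knockout and wild type. The double knockout samples carried study code NG66 in their titles, so no knockout sample shared the code NG108 with its wild-type samples. The file used here gave gene models and no value for any sample. The effect of genotype on expression was not analysed here, and the measurements below describe the annotation, with genes as units.

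The 3 genotype genes were present in the annotation with 1 transcript each. Zfp36 (NM_011756) lay on the minus strand of chromosome 7 from 28376784 to 28379228 (mm10). It had 2 exons, 957 coding bases and a 3' UTR of 774 nt, which occupied 28376784 to 28377557 in exon 2. Tnfrsf1a (NM_011609), the gene for TNFR1, lay on the plus strand of chromosome 6 from 125349723 to 125362483, with 10 exons, 1362 coding bases and a 3' UTR of 489 nt. Tnfrsf1b (NM_011610), the gene for TNFR2, lay on the minus strand of chromosome 4 from 145212368 to 145246870, with 10 exons, 1422 coding bases and a 3' UTR of 3419 nt. None of these 3 genes shared exonic bases with another annotated gene on either strand.

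The 3' UTR of Zfp36 held 3 copies of TATTTAT, the core of the site that TTP binds. Their lowest mm10 coordinates, which are their 3' ends on the minus strand, were 28376937, 28376962 and 28376977. All lay within the distal part of the 3' UTR. Tnfrsf1a had 0 copies in its 489 nt, and the 3' UTR of Tnfrsf1b was not searched because part of it was not covered by the reference transcripts. Among the other TTP family genes, Zfp36l1 had a 3' UTR of 1829 nt with 3 copies. Zfp36l2 (1825 nt) and Zfp36l3 (286 nt) were not searched for the same reason as Tnfrsf1b.

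**Figure D1:**
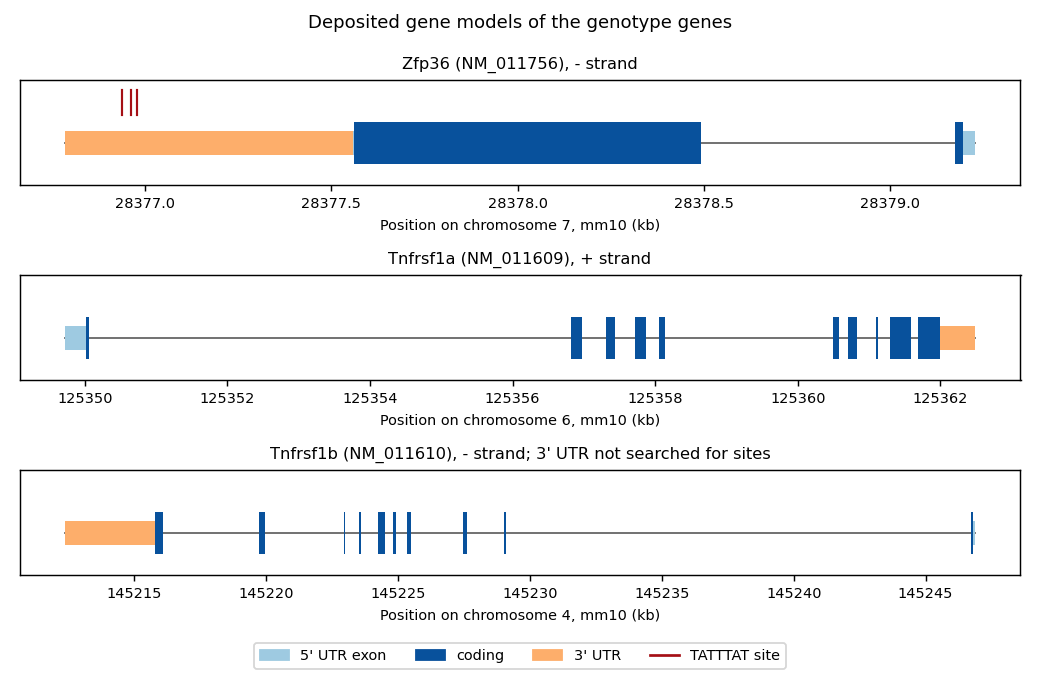
Gene models of Zfp36, Tnfrsf1a and Tnfrsf1b in the deposited annotation, drawn to scale against mm10 position in kb on a separate axis for each gene, with coding segments in dark blue, 5' UTR exons in light blue, 3' UTRs in orange and TATTTAT sites as red ticks. The 3 ticks of Zfp36 lie in its 774 nt 3' UTR, Tnfrsf1a has 0, and the 3' UTR of Tnfrsf1b was not searched.

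The 25 known TTP targets did not differ detectably in median 3' UTR length from other genes. Their median was 631 nt (interquartile range 420 to 734 nt), against 745 nt (279 to 1660 nt) for 18690 other genes. The difference in medians, targets minus others, was -114 nt (permutation test, two-sided, p = 0.651, adjusted p = 0.651). The narrower interquartile range of the targets was not tested. The longest 3' UTRs of the list were those of Lif (3180 nt), a cytokine of the interleukin-6 family, Ptgs2 (2230 nt), which encodes cyclooxygenase-2, Vegfa (1865 nt), an angiogenic growth factor, Il1a (1101 nt) and Fos (812 nt). The shortest belonged to the chemokine gene Ccl2 (274 nt), the granulocyte-macrophage growth factor gene Csf2 (318 nt), Plk3 (332 nt), Nos2 (372 nt), which encodes inducible nitric oxide synthase, and Il2 (388 nt).

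TATTTAT was present in the 3' UTR of 20 of the 23 targets that could be searched, or 87.0% (95% exact binomial interval 66.4 to 97.2%). Random lists matched on 3' UTR length had a mean share of 19.3%, with a central 95% range of 4.35 to 34.8%. The random-list p was 0.0002, the smallest that 10000 lists can give (adjusted p = 0.0004). The list was compiled partly from genes with published AU-rich elements, so this share is not independent evidence. Ptgs2 had 6 copies, Lif 5, Vegfa 3, Il1a 3, Il2 3, Plk3 3, Fos 2 and Nos2 1. Ccl2, Cxcl10 and Myc had 0 copies, and the 3' UTRs of Csf2 and Ccl3 were not searched. The 3 targets without a copy and the 2 unsearched ones were named because they complete the count, after their values were seen.

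The site was also counted in the other fixed lists. In the interferon response list, 4 of 7 searched genes carried it, among them Ifit1 and Mx1, a share of 57.1% against 19.5% in matched lists (permutation p = 0.0414, adjusted p = 0.29). In the NF-kB and TNF response list 3 of 11 genes carried it, among them Tnfaip3 and Icam1, and in the granulocyte and myeloid list 2 of 9 (Ltf and Mmp9). The genes named from these lists were picked from the carriers, outside the rule for named genes. The count was 1 of 6 erythroid genes, 1 of 7 B cell genes, 1 of 9 T cell genes, 1 of 5 NK cell genes, 2 of 4 red pulp macrophage genes, 0 of 4 dendritic cell genes, 1 of 3 plasma cell genes and 2 of 6 proliferation genes. It was 0 of 5 pancreas genes and 1 of 4 adipose genes. None of these 13 lists passed the length-matched test after adjustment over 14 lists. Each rested on only 3 to 11 searched genes, and the plasma cell list could not have passed at any share.

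**Figure D2:**
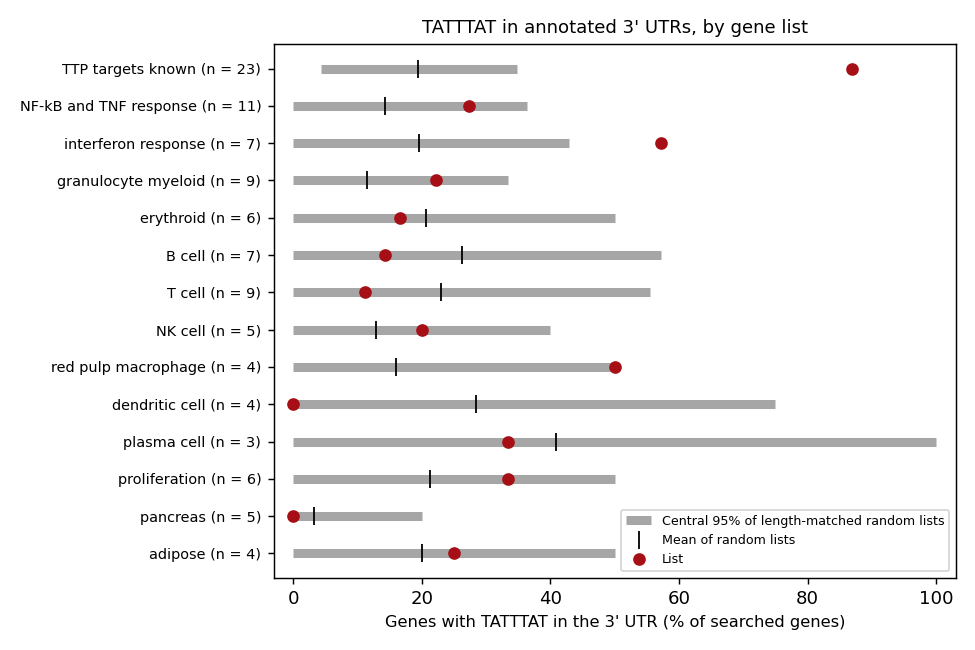
Share of searched genes with TATTTAT in the 3' UTR (x axis, percent) for the 14 fixed lists with 3 or more searched genes, with n the number searched. Red points are the lists, black ticks the mean and grey bars the central 95% of 10000 random lists matched on 3' UTR length; the known TTP targets stand at 87.0% against a bar ending at 34.8%.

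Exon overlap on the same strand limits what read counts could assign to a gene, stranded or not. Overlap on the opposite strand limits unstranded counts. Of 23337 gene symbols in the annotation, 832 shared exonic bases with another gene on the same strand and 1949 with a gene on the opposite strand. Of the 137 fixed-list genes found in the annotation, 3 overlapped on the same strand. As placed in this annotation, these were Ccl21a, with Gm1987, and the alpha-globin genes Hba-a1 and Hba-a2, with each other. Whether these genes share exons outside this annotation was not examined. On the opposite strand there were 4, namely Il1a, Nfkb2, Nfkbia and Plk3. These genes were named because they make up the counts, after the counts were seen.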

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

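No paired analysis was possible because the columns used here carry no sample values; for the same reason the alternatives planned for the genotype comparisons (normalization, tool, filter, pseudocount, left-out replicates and other wild-type groups) were not run. The difference in median 3' UTR length between known TTP targets and other genes was -114 nt and turned to 30 nt (permutation p = 0.818) with only the other fixed lists as background; the cause was not tested, and the difference was not past the threshold in any setting. It was -65 nt with the shortest and -98 nt with the median 3' UTR per gene. The targets' median stayed at 631 nt with either choice, so only the median of the other genes moved. The share of targets with a site stayed above that of length-matched lists, with permutation p = 0.0002, for the nonamer (78.3% against 10.6%), the pentamer (100% against 59.8%) and the shortest 3' UTR per gene (87.0% against 18.9%). These alternatives were not independent of the heptamer test and add little to it. Each target with the nonamer also had the heptamer, and each target with the heptamer also had the pentamer. With the shortest 3' UTR the count was 20 of 23 targets, as with the longest. Coverage by the reference transcripts limited the search to 84.7% of genes with a 3' UTR.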

Other observations

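The share of known TTP targets with TATTTAT (87.0%) was tested against explanations from the sequence and from the choice of lists; the pooled test of the other lists was chosen only after the list counts were seen. AT-rich 3' UTRs carry the heptamer more often by chance, but random lists matched on both length and AT share had a central 95% range that ended at 39.1% (permutation p = 0.0002), which argues against base composition as the whole cause. Whether single other immune or spleen lists have a share as high stays open. The length-matched test asks only whether a list exceeds random lists, not whether it reaches the targets' share. The highest share among the 13 other lists was 57.1%, in the interferon response list, but intervals for single lists were not computed. Of the 13 other lists 0 passed the length-matched test after adjustment, but the plasma cell list could not have passed at any share, and the rest had 4 to 11 searched genes. The interferon response list passed before adjustment, with 57.1% against a matched range that ended at 42.9% (permutation p = 0.0414, adjusted p = 0.29). The bound set in advance, that no list would pass, was therefore too weak to exclude this explanation. Pooled, 19 of 80 genes of those lists carried the site, 23.8% (95% exact binomial interval 14.9 to 34.6%), below the interval of the targets, which argues against a share this high in the genes of these lists as a whole, the pancreas and adipose lists included. The target list was chosen partly from genes with published AU-rich elements, so a high share was in part built into the list. The tests above cannot separate the share from that selection. None of them bears on expression in the knockout spleens.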
